A study of Gallus gallus with 2 samples.

How the data were processed

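RNA from 2 DT40 cultures was labelled with biotin and hybridised to 1-colour Affymetrix chicken arrays, 1 array per culture. The deposited table holds 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The software version, the target of the scaling and the detection calls are not given in the sources used here. In the table both arrays had a trimmed mean of 499.9 (2% left out at each end), and the signals ran from 0.07 to 53801, so the arrays had been scaled alike before deposit. MAS5 gives each probe set a signal from its own probes and scales each array by a single factor, which leaves any trend with brightness in place. Labelling starts at the 3′ end, so shorter RNA lowers the signal of probes that lie far from that end.

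The table held 38535 probe sets, of which 96 were control probe sets. The platform's annotation named 1 gene for 27178 probe sets, several genes for 177, which named none here, and none for 11180. Gene identifiers of 26863 probe sets were found in the reference, the RefSeq genes of chicken assembly GRCg7b, and 0 symbols changed. That assembly was used only for names, chromosomes and neighbours, since the table names no build. Some symbols are therefore those of the array's annotation.

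The groups came from the genotype labels. Signals were taken as deposited, values under a floor were set to the floor, and log2 was taken. The floor was the 50th percentile of all non-control signals of both arrays, 58.3, above which lay 49.4% of probe sets on the wild-type array and 50.6% on the knockout array. A gene was measured if its probe set was above the floor on at least 1 array, which held for 9486 of 13051 genes: 8042 on both, 599 in wild type only and 845 in the knockout only. Each gene was given the probe set with the highest mean log2 signal. Where 1 array was under the floor the fold is a bound, written "at least". Across non-control probe sets the log2 signals of the arrays had a Pearson r of 0.904, and 0.960 for those above the floor on both arrays, where probe sets are not independent replicates.

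The measured outcome was the log2 ratio, knockout minus wild type, with counts at 1.5-fold (1181 higher and 1506 lower), 2-fold and 4-fold. No test was made, since there was 1 array per group. For 31 gene lists and for each chromosome with at least 20 measured genes, the median log2 ratio was given its percentile among 10000 random sets of the same size drawn from the same 20 bins of mean signal, as a description of these arrays. A list was said to lie outside where it fell beyond the central 95%. In the fixed lists, 24 measured members in 15 lists were matched through a synonym in the reference, which can name a close relative or a different gene, such as NOC4L for EP400. Leaving them out moved a list's median by at most 0.20, in the list of other histone variants, and moved that of T cell markers from -0.23 to -0.03 and that of B cell identity from -0.40 to -0.37. A gene in more than 1 list counted in each.

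Named genes followed a rule. Among genes with a symbol whose other measured probe sets all went the same way, they were the 12 highest and the 12 lowest ratios measured on both arrays and, for each direction, the 4 brightest genes above the floor on 1 array only with a bound of at least 2-fold. To these were added both H2A.Z genes and, in each list described, the 4 members with the largest ratios. Other list members named in the text were chosen after their values were seen.

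Error was estimated from 3507 genes with 2 probe sets above the floor on both arrays, as the SD of the difference of their log2 ratios over the square root of 2. It holds probe error and isoform differences, not the spread between cultures or clones. Ratios of 3′ to 5′ signal came from 15 pairs of control probe sets.

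The alternatives, 9 in all, were median centring, quantile normalization and loess of the ratio on mean log2 signal (span 0.3), floors at the 25th and 75th percentile, genes above the floor on both arrays only, a pseudocount equal to the floor, the median over all measured probe sets of a gene, and leaving out probe sets shared between transcripts or genes (names ending in _s_at, _x_at or _a_at). Median centring aligned the medians of non-control probe sets above the floor on both arrays, so the gene ratios need not centre on 0 after it. The design, the lists and these alternatives were fixed before the data were examined. A further 8 lists were chosen after seeing the data: primary cilium, ERK feedback, aminoacyl-tRNA synthetases, lysosome, proteasome, mitochondrial ribosome, nucleotide synthesis and splicing factors, in which 5 measured members were matched through a synonym.

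The computation was tested on simulated data for the knockout against wild-type comparison, with 200 of 9014 genes changed and a noise SD of 0.3 per probe set. All genes changed by a log2 value of 2 in either direction passed 2-fold (100%), as did 96% of those raised by 1.5, 92% of those changed by -1.5 and 0.057% of unchanged genes. Noise was added to the simulated knockout array only, and the changed genes were drawn from genes well above the floor. Error between real probe sets was larger, with an SD of 0.38 overall and 0.50 in the dimmest genes. These percentages therefore do not describe dim genes or genes near the floor. Of 300 unshifted random lists, 4% fell outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Reporter and other probe sets with no gene named here entered no gene-level comparison; of 4956 such measured probe sets other than reporters, 256 were at least 2-fold higher and 202 lower.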

Results

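Gene expression was measured in DT40 cells, a chicken B lymphoma line that arose in the bursa of Fabricius and has long been used for gene targeting. There were 2 arrays, 1 of a wild-type clone and 1 of a clone that lacked both genes for H2A.Z, the histone variant that replaces H2A in nucleosomes around many promoters. In that clone the H2A.Z-2 gene was removed for good, while H2A.Z-1 came from a transgene that tetracycline switched off, and RNA was taken after 3 days of tetracycline. The labels used here give no tetracycline treatment for the wild-type array, so the drug goes with the genotype. The comparison asks which transcripts differ between wild-type cells and cells without H2A.Z-2 and with the H2A.Z-1 transgene switched off. There was no array of the same clone without tetracycline, so effects of the lasting and of the 3-day loss cannot be told apart. With 1 array per group there were no replicates, so no difference below has a replicate check and no test was made; genes are not replicates, and the number of arrays limits the precision. Each value is the MAS5 signal of a gene's brightest probe set, and each log2 ratio is the knockout array minus the wild-type array. Of 13051 genes on the array, 9486 were measured, that is, above a signal floor of 58.3 on at least 1 array.

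Both targeted genes had very bright probe sets on the wild-type array and dim ones on the knockout array. H2A.Z-1, listed as H2AFZ on chromosome 4, had a signal of 27331 in wild type and 387 in the knockout, which is 70.6-fold lower and leaves 1.42% of the wild-type signal. H2A.Z-2, listed as H2AZ2 on chromosome 22, had a signal of 18244 in wild type and 17.6 in the knockout, under the floor, and so was at least 313-fold lower. Each gene had 1 measured probe set, and that of H2A.Z-1 was of the type shared between transcripts or genes (name ending in _s_at). Whether these probes lie inside the removed parts of the genes, or detect the transgene, was not examined here. The 1.42% is therefore not a measure of how far the transgene was switched off.

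Away from the targets, the fixed lists of cholesterol and fatty acid synthesis, the amino acid and unfolded protein response, glycolysis and hypoxia, and immediate early genes had higher medians on the knockout array than matched random lists. That of B cell identity had a lower one, which lay inside the random range when probe sets shared between transcripts were left out. Over all measured genes, 367 genes were at least 2-fold higher and 628 at least 2-fold lower, so that 63.1% of these genes were lower. That split depended on scaling. Median centring, which aligned the medians of probe sets and not of genes, gave 523 higher and 458 lower genes, or 46.7% lower. It moved the median log2 ratio of all measured genes away from 0, from 0.02 to 0.15. Quantile normalization and loess kept more lower than higher genes, with 55.9% and 59.0% lower. The split also depended on the floor, with 51.04% lower when the floor was set at the 25th percentile. At 4-fold, 27 genes were higher and 69 lower. Gene lists are therefore described against random lists matched on brightness, which shift with the arrays.

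Among named genes above the floor on both arrays, the highest ratio was that of NEURL2, an adaptor of ubiquitin ligases, with a signal of 81.6 in wild type and 1501 in the knockout, 18.4-fold higher. CHAC1, an enzyme that breaks down glutathione and a target of ATF4, went from an already bright 1493 to 13301, 8.91-fold higher. SC5D, an enzyme of the last steps of cholesterol synthesis, was 7.58-fold higher. Others among the 12 highest were MAT1A, which makes S-adenosylmethionine (log2 ratio 2.92), the alanine transaminase GPT2 (2.47, another probe set at 0.61), the retinol dehydrogenase RDH11 (2.45) and the lipoprotein receptor LRP8 (2.83). The transcription factors MAFF (2.89), KLF6 (2.41) and ETV5 (2.26) belonged to them too, with MBP (2.37, another probe set at 0.072) and FAM208B (2.17, another at 0.52). Among genes above the floor on the knockout array only, the brightest were HHLA2, a B7-family ligand, at least 6.76-fold higher, the stress factor ATF3, at least 6.54-fold higher, OSTN, at least 6.25-fold higher, and the activation marker CD83, at least 5.49-fold higher.

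Among named genes above the floor on both arrays, the lowest ratios after H2A.Z-1 belonged to KCNMB1 and DCX. KCNMB1, a subunit of a calcium-activated potassium channel, had a log2 ratio of -3.63, and DCX, a microtubule-binding protein best known from migrating neurons, of -3.58. DCX had signals of 2024 in wild type and 169 in the knockout, but the weakest of its 3 measured probe sets had a log2 ratio of only -0.72. The kinase STK17A (log2 ratio -3.58), the endocytic protein NECAP1 (-3.16), the signalling protein CHN2 (-3.07, another probe set at -0.55), the butyrophilin BTN1A1 (-2.92), the phosphoinositide phosphatase MTMR1 (-2.60) and FAM110D (-3.09), JMJD7 (-2.92), TVP23A (-2.92, another probe set at -0.52) and CA3B (-2.74) completed the 12 lowest. Of genes above the floor in wild type only, PINLYP was at least 21.0-fold lower and PACSIN3 at least 17.4-fold lower. TNFSF13B, which encodes the B cell survival factor BAFF, was at least 15.3-fold lower.

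**Figure D1:**
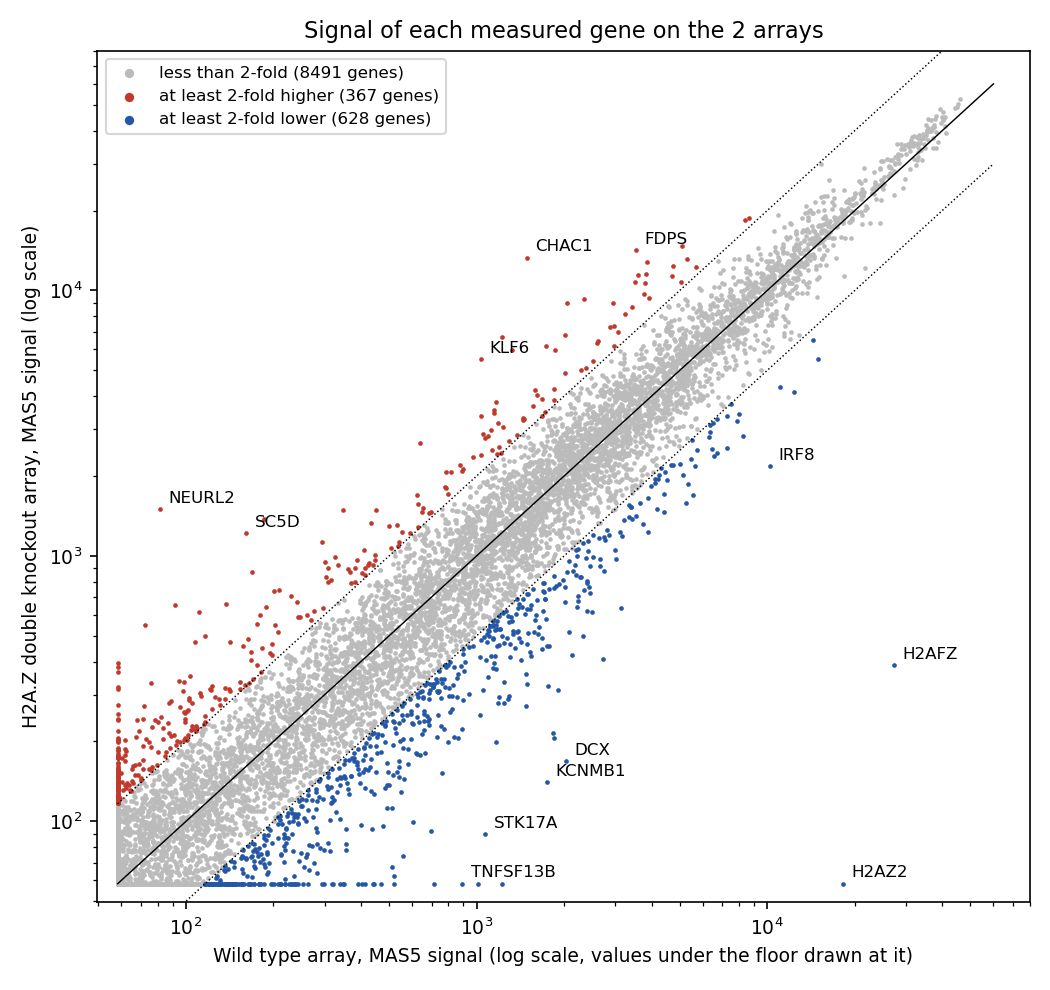
Each point is 1 of 9486 measured genes, with its MAS5 signal on the wild-type array on the x axis and on the knockout array on the y axis, both on log scales and with values under the floor drawn at the floor of 58.3. Red points (367 genes) lie at least 2-fold above the diagonal, blue points (628 genes) at least 2-fold below it, a split that turns to 523 and 458 under median centring, and H2AFZ and H2AZ2 lie far below all other bright genes.

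Genes of cholesterol and fatty acid synthesis were higher almost as a block. Of 24 measured members, 22 were higher and 15 of these at least 2-fold, with a median log2 ratio of 1.11, above all 10000 matched random lists (percentile 100, central range -0.11 to 0.21). Besides SC5D, the farthest were FDPS, which makes farnesyl diphosphate (3549 to 14184), SREBF2, the transcription factor that drives the pathway (3.38-fold higher), and the sterol carrier STARD4 (3.21-fold higher). The pathway was covered from its start to its end, with HMGCS1 at 1.18, MVK at 1.28, FDFT1 at 1.11, LSS at 1.67 and DHCR7 at 1.09 (with another probe set at 0.031) on the log2 scale. The fatty acid genes ACLY (1.54) and SCD (1.44) were higher too. Only PMVK (-0.13) and SREBF1 (-0.20), the latter close to the floor, were lower.

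Genes of the amino acid response and the unfolded protein response were also higher, with 28 of 32 members on that side, 7 of them at least 2-fold, and a median log2 ratio of 0.40 (percentile 100). The highest members were CHAC1, ATF3 (bound 2.71), the serine synthesis enzymes PSPH (2337 to 9287, 3.97-fold) and PSAT1 (3.09-fold), and the cystine transporter SLC7A11 (3.78-fold, but on a dim probe set, from 71.7 to 271, with another of its 3 at 0.088). ATF4 itself, the transcription factor of this response, was 1.60-fold higher. Among chaperones of the endoplasmic reticulum, HSPA5, the main one, had a log2 ratio of 0.18 and HSP90B1 of 0.10, while CALR was lower at -0.56. ASNS, a usual target of ATF4, was not higher (-0.19).

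In the glycolysis and hypoxia list, 23 of 28 members were higher and the median was 0.31 (percentile 99.95). The glycolytic enzymes PFKL (3.35-fold) and ENO2 (3.17-fold), the mitophagy receptor BNIP3 (2.58-fold) and the glucose transporter SLC2A1 (2.24-fold) led it, while HIF1A, which encodes the hypoxia-inducible factor itself, was lower (-1.01).

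**Figure D2:**
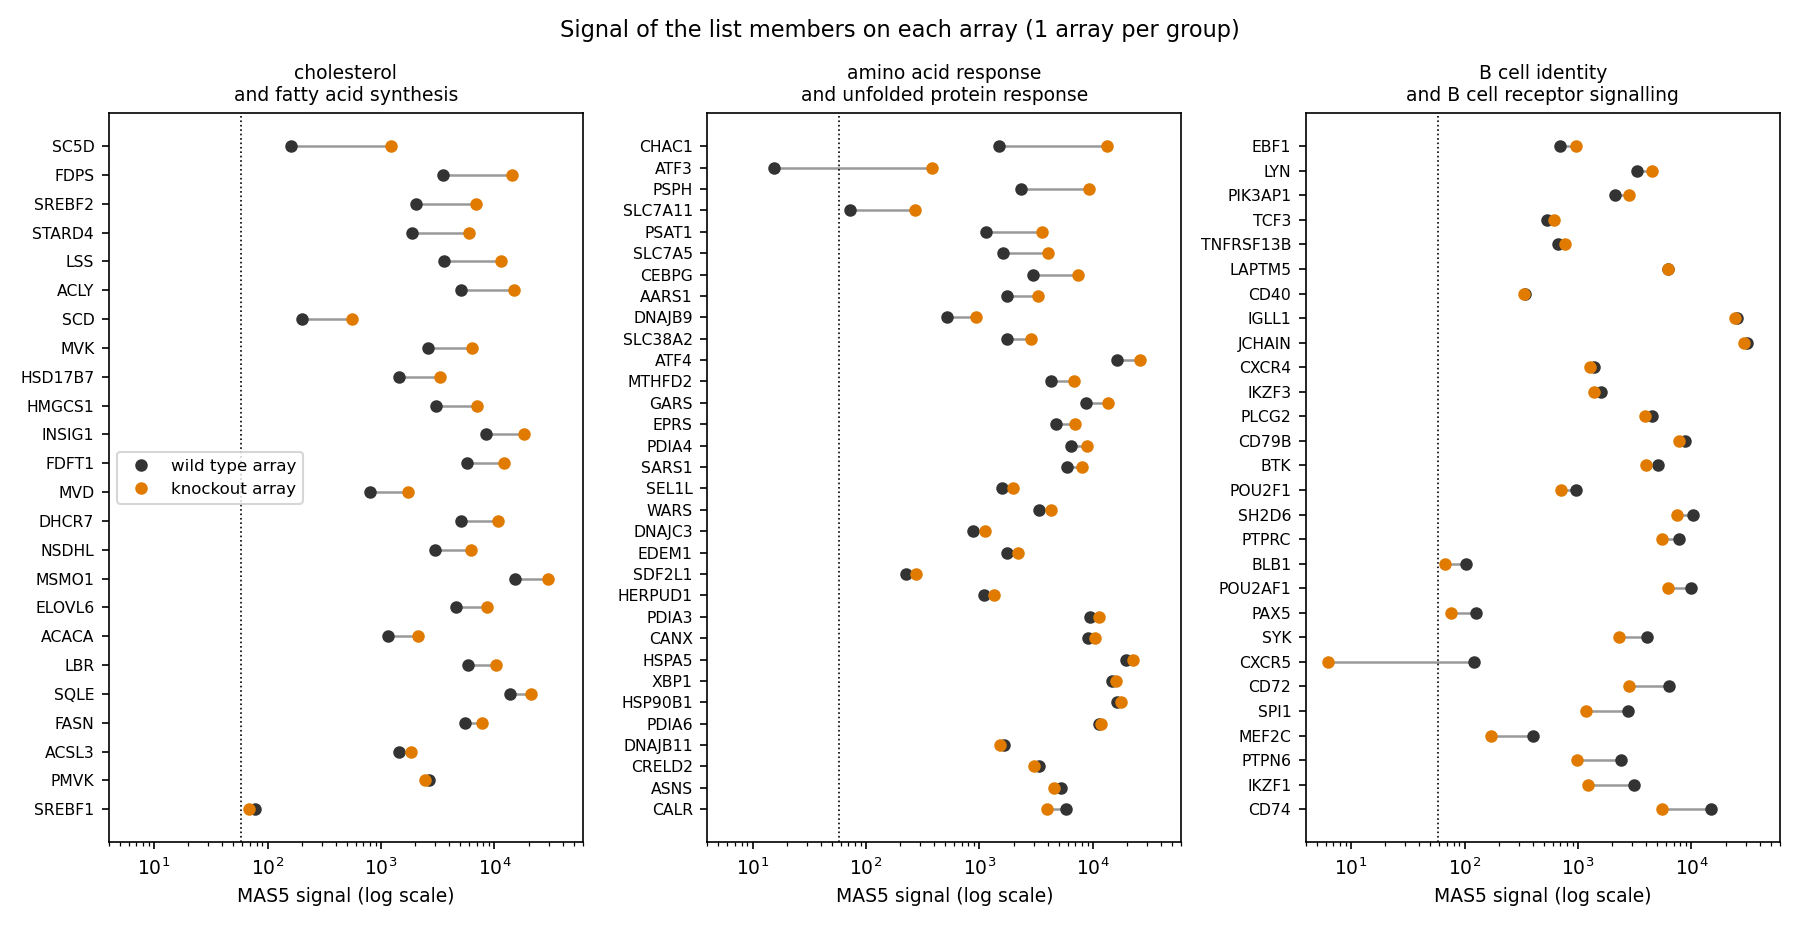
MAS5 signal on a log scale for the measured members of 3 fixed lists, with the wild-type array in black, the knockout array in orange, 1 array per group and the floor as a dotted line. The orange points lie to the right for 22 of 24 cholesterol and fatty acid genes and 28 of 32 amino acid and unfolded protein response genes, and to the left for 22 of 28 B cell genes. LBR and SH2D6 entered their lists through synonyms.

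Immediate early genes, which respond to growth factors and stress without new protein synthesis, had a median log2 ratio of 0.98 (percentile 100), with 13 of 15 members higher and 7 at least 2-fold. KLF6 was 5.32-fold higher, and the lowest of its 3 measured probe sets still had a log2 ratio of 1.56. The MAP kinase phosphatase DUSP4 was 4.17-fold higher, JUN 3.26-fold and KLF2 2.51-fold, while NR4A2 and ZFP36L1 were lower. In the interferon and innate response list the median was 0.39 (percentile 99.73), with 14 of 22 members higher. Its highest members were NFKBIZ (1.62), NFKB2 (bound 1.59), the transcription factor IRF1 (1.57), TNFAIP3 (1.42) and NFKBIA (1.24). The antiviral genes OASL and IFIT5 stood near the floor, at bounds of 0.37 and -0.01. This median was inside the random range with the floor at the 25th percentile (94.15) or the 75th (96.59), and without probe sets shared between transcripts (94.49).

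Genes of MYC and ribosome biogenesis were slightly higher, with 28 of 34 members on that side, none at 2-fold, and a median of 0.25 (percentile 99.83). MYC itself, one of the brighter transcripts of the array, had a log2 ratio of 0.23, and DKC1, needed for ribosomal RNA modification, of 0.57. The farthest members were DDX18, lower (-0.995), and DDX10, higher (0.85, with another probe set at -0.16). Among ribosomal proteins 56 of 58 were higher, but by little, with a median of 0.17 (percentile 99.62). Neither list was outside its range under every setting: the first fell to 0.06 (percentile 54.06) without shared probe sets and to 0.08 (78.12) with all probe sets of each gene, and the second to 0.04 (96.94) after loess and 0.16 (96.445) without shared probe sets.

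B cell genes were lower on the knockout array. Of 28 measured members of the list of B cell identity and B cell receptor signalling, 22 were lower, 7 of them at least 2-fold, and none was at least 2-fold higher; the median was -0.40 (percentile 0.01). The bright members CD74, the invariant chain of MHC class II (14969 to 5510), and IKZF1, a lymphoid transcription factor (3113 to 1232), were 2.72-fold and 2.53-fold lower. The phosphatase PTPN6 was 2.42-fold lower and the transcription factor MEF2C 2.39-fold lower, with SPI1 and CD72 at -1.23 and -1.16. PAX5, the factor that maintains B cell identity, had a log2 ratio of -0.73 but on a dim probe set, from 126 to 76.3. The receptor component CD79B (-0.19), the kinases BTK (-0.37) and LYN (0.44) and the surface receptor CD40 (-0.04) were all within 1.5-fold of wild type. The list's median was -0.25 under median centring and -0.19 with the floor at the 75th percentile, outside the range in both, and without probe sets shared between transcripts it was -0.19 and lay inside the random range (percentile 5.33).

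In the plasma cell and germinal centre list, 6 of 10 members were lower, with a median of -0.37 (percentile 0.31). IRF8, a factor of germinal centre B cells, accounted for the farthest value, from 10229 to 2182 or 4.69-fold lower, followed by CREB3L2 (-1.26, although its 6 probe sets ranged from -2.37 to 0.47), ELL2 (-0.76) and the coactivator POU2AF1 (-0.67). The plasma cell factors XBP1 (0.13) and IRF4 (0.09) differed little. This median was inside the random range at either other floor (-0.10 at both) and was 0.003 without shared probe sets; under median centring it was -0.22, outside the range.

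Measured genes of the complexes that place and remove H2A.Z were lower, at a median of -0.31 (percentile 0.37), with 22 of 27 members on that side and 4 at least 2-fold. SRCAP, RUVBL2 and ZNHIT1 were not found on the array, and NOC4L entered in place of EP400 through a synonym. Neither SRCAP nor EP400 was therefore measured. Leaving out members matched through a synonym kept the list's median at -0.31. Under median centring the median was -0.15 (percentile 0.52), and without shared probe sets it was still -0.31 but lay just inside the random range. Examples were ING3, a subunit of the NuA4/TIP60 acetyltransferase, 2.08-fold lower, EPC1 of the same complex, 1.97-fold lower, and the INO80 subunits INO80C, 2.29-fold lower, and INO80D, 2.52-fold lower but with another probe set at 0.04. The H2A.Z chaperone ANP32E had a log2 ratio of -0.31. The other histone and chromatin lists were inside their ranges as deposited. The histone variants had a median of -0.08 over 4 genes, which turned to 0.07 under median centring, and included the macroH2A gene H2AFY (-0.47). The histone chaperones had a median of 0.03, which turned to -0.02 after loess or quantile normalization and to -0.07 with all probe sets of each gene, with CABIN1 lower (-1.36) and RBBP7 higher (0.65). For Polycomb and DNA methylation the median was 0.20, turning to -0.12 with the floor at the 75th percentile and outside the range after loess (0.28, percentile 97.96), with TET1 lower (-0.93) and PCGF1 (0.95) and DNMT3A (0.85, with another probe set at 0.060) higher.

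The G2/M and mitosis list had 28 of 43 members lower and a median of -0.13 (percentile 0.80), a direction that flipped to 0.03 under median centring although the percentile stayed at 0.78. It was inside the range after quantile normalization (4.555) or loess (2.715) and without shared probe sets (8.77). Its farthest members were the cytokinesis factors ECT2, 2.23-fold lower with another probe set at -0.12, and RACGAP1, 1.95-fold lower with probe sets that went both ways, and the kinetochore motor CENPE, 1.76-fold lower, while CCNB1 (0.13) and TOP2A (0.20) were slightly higher. Genes of G1/S and DNA replication had a median of -0.08, turning to 0.07 under median centring, and were inside the range, with the primase subunit PRIM1 lower (-1.44) and POLA2 higher (0.95). Centromere and kinetochore genes had a median of -0.16, close to 0 under median centring (-0.006). DNA repair genes were at -0.14, close to 0 under median centring (-0.004), but held the E2 enzyme of the Fanconi pathway UBE2T, 4.93-fold lower, along with FANCC (-1.32), RAD51B (-1.25) and RAD50 (-1.14). In the p53 list (median -0.20) MDM2 was lower (-1.17) and GADD45A higher (0.93), and in the apoptosis list (median -0.29) the killer proteins BIK (2.10) and BAK1 (1.24) were higher and CASP6 (-1.29) lower. Both of these medians were inside their ranges.

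The mitochondrial respiratory chain was lower relative to other bright genes. Its median was -0.09 (percentile 0.04), a direction that flipped to 0.07 under median centring with the percentile at 0.01. The 4 farthest members were NDUFB10, 2.44-fold lower, NDUFV3, 2.34-fold lower, and NDUFB9, 1.69-fold lower, all of complex I, with UQCRB of complex III, 1.78-fold lower with 3 probe sets that went both ways. When all probe sets of each gene were used, the median was -0.02 and lay inside the range (percentile 17.06). The oxidative stress, heat shock, cytoskeleton and housekeeping lists were inside their ranges, with medians of 0.17, 0.14, 0.15 and 0.14. NQO1 (0.73) and GPX1 (0.63) were among the oxidative stress genes that were higher.

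**Figure D3:**
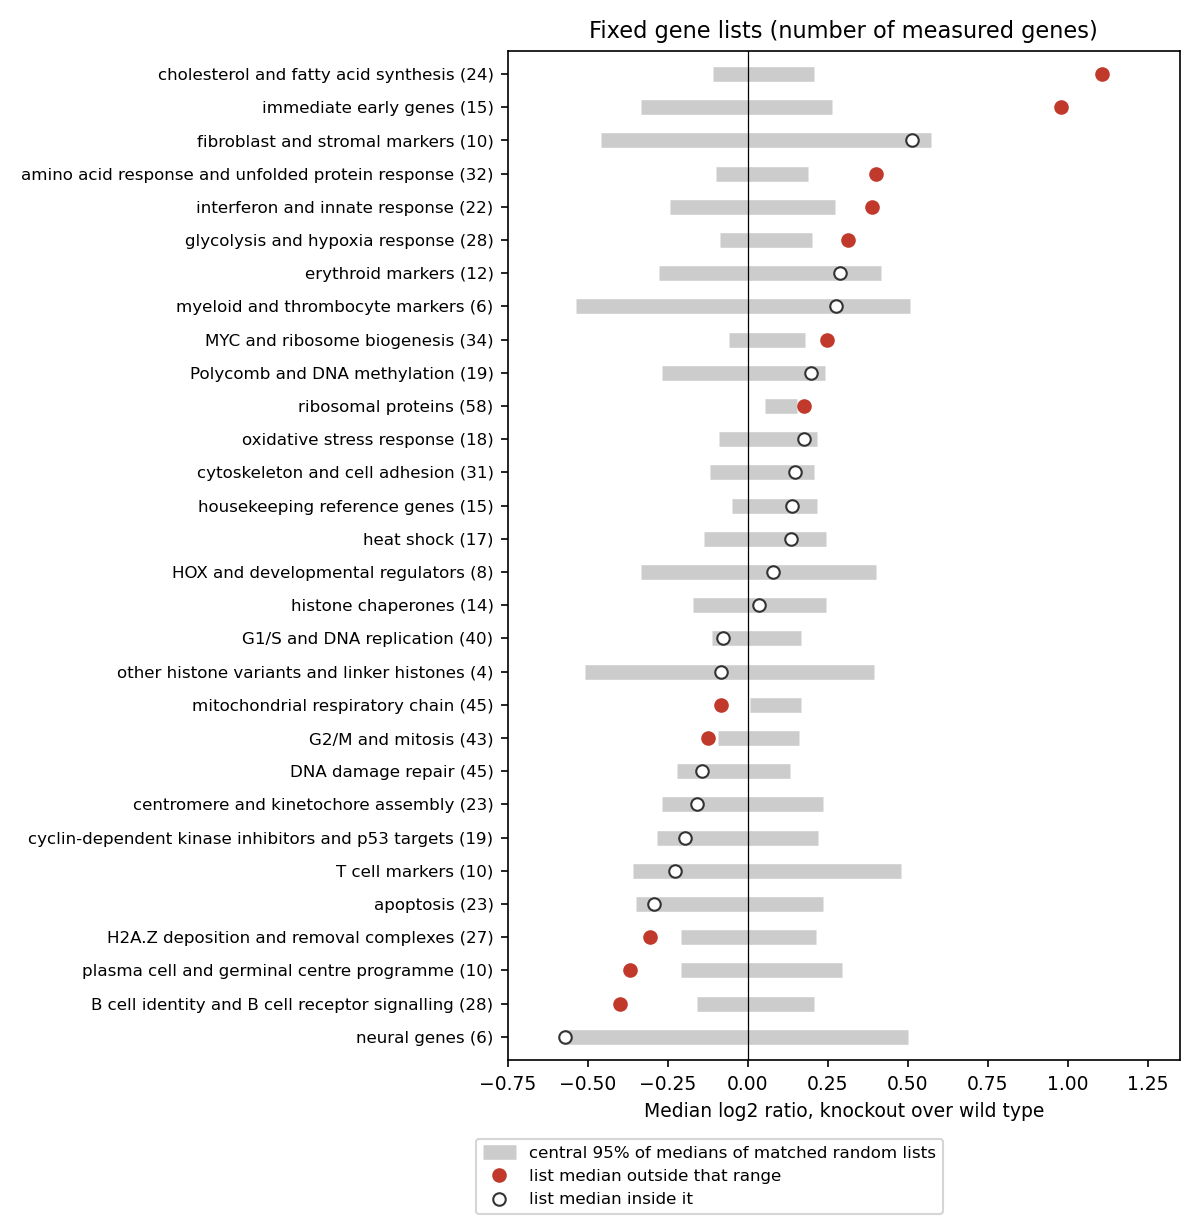
Median log2 ratio of each fixed gene list other than the targets, knockout over wild type, with the number of measured genes in brackets. Grey bars give the central 95% of medians of 10000 random lists matched on size and brightness, and filled points are lists outside it, from 1.11 for cholesterol and fatty acid synthesis to -0.40 for B cell identity; the medians of G2/M and mitosis and of the respiratory chain turn positive under median centring.

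Markers of other cell types gave no list outside its range. The medians were -0.23 for T cell markers, 0.28 for myeloid and thrombocyte markers, 0.29 for erythroid markers, 0.51 for fibroblast and stromal markers and 0.08 for HOX and developmental regulators, over 6 to 12 genes each, many of them near the floor. These medians moved with the setting: that of T cell markers turned to 0.12 with genes above the floor on both arrays only and was -1.17 with the floor at the 75th percentile, and that of fibroblast markers ran down to 0.036 at the same floor. CD3D was bright, with 12407 in wild type and 4162 in the knockout, 2.98-fold lower. FN1, the fibronectin gene, was 2.55-fold higher at a low level (122 to 312). The neural list stood at the edge, with a median of -0.57 and a percentile of 2.51 over 6 genes, of which DCX and the microtubule-associated protein MAP2 (1425 to 475) were bright; it turned to 0.042 (percentile 48.88) with the floor at the 25th percentile. In all, 13 of the 31 fixed lists were outside the central 95%, and 1 of the 13 is the list of the targeted genes themselves, which is outside by design. Lists of randomly drawn genes would give 1.55. Genes of 1 pathway can vary together and some genes are in more than 1 list, so that number is no measure of chance for these lists.

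By chromosome, named on the GRCg7b assembly, the medians of 31 chromosomes ran from -0.14 to 0.24. There were 6 outside the range of matched random sets, where sets of randomly drawn genes would give 1.55. Chromosome 2 was lower at -0.08, turning to 0.06 under median centring, and chromosomes 12 (0.10), 16 (0.24), 24 (0.14), 25 (0.21) and 27 (0.13) were higher. Only chromosomes 2 and 25 were outside in each alternative. Chromosome 24 turned to -0.04 with the floor at the 75th percentile and was inside under median centring, with the pseudocount (95.27) and with genes above the floor on both arrays only (86.87). Chromosome 12 was inside in 5 alternatives, with a percentile of 53.335 without shared probe sets, chromosome 16 with genes above the floor on both arrays only (97.31) and with all probe sets of each gene (96.01), and chromosome 27 under median centring (96.91) and with the floor at the 25th (85.74) or 75th percentile (92.955).

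The 2 arrays differed in the ratio of 3′ to 5′ signal of control transcripts. It was higher on the knockout array for 13 of 15 pairs of control probe sets, with a median log2 change of 0.64 over all pairs. Many pairs are repeat designs for the same spiked-in bacterial transcripts, so the pairs are not independent. Spiked-in transcripts also do not come from the cells, so they cannot show the state of the cells' RNA. Among chicken transcripts the ratio went from 1.13 to 1.95 for ACTB and from 1.23 to 1.46 for EEF1A1, but only from 1.03 to 1.07 for GAPDH. For the spike dap it was 2.12 in wild type and 4.28 in the knockout in 1 design. For the spike lys the log2 change was 0.28, -0.37 and -0.21 in its designs. The difference between the arrays in 3′ to 5′ signal may bear on any gene group described here. That was not tested, because probe positions along transcripts were not used. Error between probe sets of 1 gene was 0.24 (SD per probe set, log2) for the brightest 877 of 3507 genes and 0.50 for the dimmest 877. Among 276 genes whose brighter probe set differed at least 2-fold, another probe set went the same way in 248 (89.9%) and was itself at least 2-fold in 123.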

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

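The test of culture conditions and clones was chosen only after the result was seen. Some reporter probe sets, which name no chicken gene and enter no comparison of genes, were bright on the knockout array alone. Of 57 there were 4 above 1000 there, with signals of 23488, 10449, 1778 and 1769, while none of the 4 exceeded 20.1 on the wild-type array. The other 53 reporter probe sets reached at most 213 on the knockout array and 131 on the wild-type array. Which sequences these 4 represent was not examined here, and no explanation was tested.

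More genes were at least 2-fold lower than higher on the knockout array. Scaling between the arrays is a candidate cause. The ratio of lower to higher genes was 1.71 as deposited, 1.44 after loess, 1.27 after quantile normalization and 0.876 after median centring. Of these scalings, median centring alone turned the excess, and it moved the median log2 ratio of all measured genes from 0.02 to 0.15. The excess is therefore not firm. Shorter labelled RNA on the knockout array stays open. Other probe sets of the same genes kept more of the log2 ratio in 178 lower genes (0.735) than in 98 higher genes (0.521), a difference of 0.214 with a bootstrap interval of 0.069 to 0.312, and of 0.095 (-0.047 to 0.190) under median centring. The prediction had taken such a value to count against shorter RNA, but it does not, because the brightest probe set was kept for each gene and the others may lie farther from the 3′ end.

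Genes of cholesterol and fatty acid synthesis were higher on the knockout array. A trend with brightness or scaling would have been removed by loess, after which the median was still 1.04 and above the random range. The random lists were already matched on brightness, so only the size of the median bears on this, not its place against them. Error of single probe sets is also argued against, since 15 other probe sets of 10 of these genes had a median log2 ratio of 0.699 (bootstrap over genes 0.524 to 0.937). Differences in culture, such as serum lipids or cell density, or between clones, and tetracycline itself, which the labels give for the knockout array only, cannot be told apart from the loss of H2A.Z, because there was 1 array per group. A sterol response to the loss of H2A.Z is 1 hypothesis that would need replicate cultures and other clones.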

How the results depend on the processing

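No paired analysis was possible because there was 1 array per group. With no replicates, a moved value below is one that crossed a fixed limit, not a test. H2A.Z-1 stayed between -6.17 and -5.94 in each alternative that kept its probe set. Of 13 lists outside their range, 5 stayed outside in the same direction under all 9 alternatives: the H2A.Z genes, cholesterol and fatty acid synthesis, the amino acid and unfolded protein response, glycolysis and hypoxia, and immediate early genes. Of the other 18, 11 stayed inside throughout. Of 1253 values of 147 named genes under the alternatives, 1146 moved little, 106 moved more and 1 reversed. Where an alternative changed the genes or probe sets used, that is its construction; otherwise the cause was not tested. Dim signals are 1 limit: the dimmest of 4 groups of genes had an error SD of 0.50.

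Median centring moved the median log2 ratio of all measured genes to 0.15. It reversed G2/M (0.027), the respiratory chain (0.067) and chromosome 2 (0.061), and brought chromosomes 24 (0.29) and 27 (0.26) inside the range. Quantile normalization put fibroblast markers (0.60) and neural genes (-0.64) outside and G2/M (-0.11) and chromosome 12 (0.10) inside. Loess put Polycomb and DNA methylation (0.28), fibroblast markers (0.58) and neural genes (-0.64) outside and G2/M (-0.13), ribosomal proteins (0.038) and chromosome 12 (0.065) inside.

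With the floor at the 25th percentile, 1172 genes were at least 2-fold higher and 1222 lower, H2A.Z-2 was above the floor on both arrays with a log2 ratio of -10.02, neural genes turned (0.042), plasma cell genes (-0.10), the interferon list (0.32) and chromosome 27 (0.10) were inside and erythroid markers (1.09) outside. At the 75th percentile the counts were 130 and 292, the bound was -5.89, chromosome 24 reversed (-0.044), Polycomb and DNA methylation turned (-0.12), plasma cell genes (-0.10), the interferon list (0.37) and chromosome 27 (0.093) were inside and T cell markers (-1.17) and neural genes (-1.59) outside; myeloid and HOX lists gave no value. With genes above the floor on both arrays only, T cell markers turned (0.12), neural genes (-0.57) were outside and chromosomes 12 (0.069), 16 (0.24) and 24 (0.069) inside, and H2A.Z-2 gave no value. With the pseudocount H2A.Z-2 was at -7.91, T cell (-0.39) and erythroid markers (0.44) were outside and chromosome 24 (0.11) inside.

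With the median of all probe sets, the p53 list (-0.30) and oxidative stress (0.21) were outside, and MYC and ribosome biogenesis (0.083), the respiratory chain (-0.019) and chromosomes 12 (0.036) and 16 (0.17) inside. Without shared probe sets, H2A.Z-1 gave no value, CREB3L2 (0.47) and the plasma cell list (0.0033) reversed, oxidative stress (0.30) was outside, and the H2A.Z complexes (-0.31), B cell identity (-0.19), G2/M (-0.086), MYC and ribosome biogenesis (0.063), ribosomal proteins (0.16), the interferon list (0.24) and chromosome 12 (0.0095) were inside.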

Other observations

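The lists in this part were chosen after seeing the data, and the chromosome tests and the test of the cilium list under loess were chosen, and the test of its other probe sets was renamed, only after their results were seen. Genes of the primary cilium, the antenna-like organelle built on the centriole of resting cells, were lower on the knockout array. The list was drawn up after TCTN1, DYNC2LI1 and ENKUR had been noticed among the lowest genes and leaves those out. Of its 52 measured members 42 were lower, 19 at least 2-fold, and 0 were at least 2-fold higher, with a median log2 ratio of -0.66. Examples were the intraflagellar transport genes IFT22 (890 to 224, log2 ratio -1.99), IFT81 (-1.43) and IFT27 (-1.19), and IFT46, which was under the floor on the knockout array (402 in wild type, bound -2.79). TMEM67, WDR35 and WDR19 were under the floor there too, and such genes could only come out lower. Among the 48 members above the floor on both arrays the median was also -0.66. Also lower were TCTN2 at -1.65, ARL6 at -1.38, MKS1 at -1.13 and BBS5 at -1.10 (another of its probe sets at 0.11), while TCTN3 (0.091), BBS2 (0.11), BBS7 (0.22) and RPGRIP1L (0.25) were not, and IFT57 (0.83) and KIFAP3 (0.81) were higher.

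Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher, at a median of 0.45 (percentile 99.99), with 14 of 18 on that side, led by QARS (1.34, another probe set at -0.074), YARS (0.94) and IARS (0.93); EPRS, GARS and 3 more of these genes were already in the amino acid response list. Over the 9 alternatives the median ran from 0.26 to 0.65. Mitochondrial ribosomal proteins had a median of -0.12 (percentile 0.48), a direction that flipped to 0.03 under median centring, with 34 of 52 lower, among them MRPL47 (-1.73) and MRPS14 (-1.54). Medians inside the random range were those of lysosome genes (-0.08, turning to 0.07 under median centring), the proteasome (0.10), nucleotide synthesis (-0.07, turning to 0.08) and splicing factors (0.02, turning to -0.06 after loess).

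The hypothesis that cilium genes as a class are lower in the knockout was examined on the list without TCTN1, DYNC2LI1 and ENKUR. Its median lay at percentile 0 of 10000 matched random lists, and between -0.67 and -0.50 over the 9 alternatives. The list was drawn up after the data were seen and kept very low genes such as IFT46 (bound -2.79). The percentile is therefore a description and not a test on unseen members. Scaling or a brightness trend is argued against by a median of -0.545 after loess, and error of single probe sets by 28 other probe sets of 18 of these genes, whose median was -0.404 (bootstrap over genes -0.602 to -0.155). The latter was first written as a test of shorter RNA, and its bounds were kept. Shorter RNA on the knockout array, the growth state of the cultures, tetracycline and differences between clones were not tested for this list and stay open. This list was weighed in place of the B cell list after the results of both were seen; for the B cell list 24 other probe sets of 14 genes had a median of -0.379 (-1.46 to -0.10).

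A second hypothesis was that feedback genes of ERK signalling are higher, after DUSP4 and ETV5 had been seen. Of 11 other members 10 were higher, among them KLF10 (1.32, another probe set at 0.12), ELK3 (0.83), SPRY2 (0.76) and SPRED2 (bound 1.67), and CCND1 was lower (-0.45). ETV4 (0.030), MYC (0.23) and EGR1 (bound 0.20) count among the 10 but were close to wild type. EGR1, SPRED2 and SPRY4 (bound 0.93) were under the floor in wild type, so they could only come out higher. Among the 8 members above the floor on both arrays the median was 0.63. The median of the 11 was 0.76, at percentile 99.99, and over the alternatives it stayed between 0.59 and 0.91. This list too was drawn up after the data were seen, so the percentile is a description. Of the 11, 4 (EGR1, MYC, DUSP5 and KLF10) were also in the fixed list of immediate early genes, so the lists are not independent, and a difference in serum or growth between the cultures may give the same picture.

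Another hypothesis, that the targeted changes disturb the genes around both H2A.Z loci as a set, was not borne out. The 20 measured genes nearest to the 2 loci, 5 on each side, had a median absolute log2 ratio of 0.28, at percentile 25.46 of runs of adjacent genes, and 1 of them, DAPP1 (-1.25), was at least 2-fold apart. Such a median cannot show a change of only a few adjacent genes. The nearest measured genes on either side of H2AFZ were PPP3CA at -0.77 (1734 to 1020) and DNAJB14 at 0.16. Those of H2AZ2 were GMCL1 at 0.06 and TACR1, near the floor, at -0.05. Genes that were not measured were passed over, so closer genes may lie between. On the deposited scaling, a gain or loss of a whole chromosome in the knockout clone was argued against for the 29 chromosomes with at least 50 measured genes, where the median farthest from 0 was 0.208 on chromosome 25 and all bootstrap bounds lay between -0.15 and 0.30. Under median centring, which moved the median of all measured genes to 0.15, chromosome 25 was at 0.36, past the limit of 0.3 used here. For the 2 chromosomes with fewer genes it stays open, since the median of 0.241 on chromosome 16 rests on 28 genes and the bounds reached 0.53.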
